A study of Homo sapiens with 6 samples.

How the data were processed

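Total RNA depleted of ribosomal RNA from HT1080 cells was sequenced in 3 WT and 3 TOP3B knockout libraries. The deposited tables hold an estimated count and an RPKM value per gene and library. The submitters' processing notes name Salmon 1.10.1 and the hg19 build, and the part each played is not given in the sources used here. The RPKM values allowed the estimated count to be compared with whole numbers. In 442 values the median distance of the implied count from a whole number was 0.237, so the deposited counts are rounded estimates. The length implied by count and RPKM followed the mean genomic span of a gene's transcripts (Spearman's rho 0.983 across 10895 genes, which are not independent replicates, with 67.5% within 3%).

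The count table held 35820 genes. Of these, 31807 matched a GENCODE v29 symbol and 3740 a gene name table, 99.2% in all, and 273 did not match. Positions are from GENCODE v29 on GRCh38, and no hg19 position is used. One entry was named differently in the count and RPKM tables, as E2F1 and E2F2, and was left out. Library totals lay between 17919106 and 20475280 counts. Floors and binomial intervals cover counting error only, and bootstrap intervals cover the spread between genes.

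Genes were filtered with filterByExpr and tested with edgeR 4.0.16 (TMM scaling, quasi-likelihood F test) in R 4.3.3, with Benjamini-Hochberg adjustment over 13965 genes and a threshold of 0.05. Fold changes are knockout over WT. Standard errors were derived from the F statistic. With 3 libraries per group the model has 4 residual degrees of freedom. CPM values use TMM-scaled library sizes. Groups followed the labels. The WT labels carry replicate numbers and the knockout labels do not, so knockout numbers follow the order of deposition and no pairs were formed. The series text names HCT116 once for the WT cells, whereas the sample labels name HT1080.

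Choices were fixed before the data were examined, including 33 gene lists, the alternatives and the rule for named genes. The rule named TOP3B, the 7 largest rises and 7 largest falls among called genes with a mean of at least 2 CPM and the 3 knockout libraries on 1 side of the 3 WT libraries, and at most 2 called genes per list with the largest changes and a mean of at least 1 CPM, 1 per direction where both had calls. Lists without a called gene gave the 2 most abundant members. Pseudogenes and antisense genes that a symbol prefix had brought into a list were removed after the data were seen. Genes named outside the rule are stated as such. The 31 lists with at least 5 measured members, the chromosomes and the genes within 5 Mb of TOP3B were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry for the lists.

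The alternatives were DESeq2 1.42.0, limma-voom, limma-trend on log2 RPKM with a pseudocount of 1 or 0.1, DESeq2 size factors, upper quartile scaling, library size alone, library sizes without the 100 most abundant genes, no filter on low counts, a filter of 1 CPM in 3 libraries, robust dispersion, a test against a fold of 2 and each library left out. Chromosome tests with a library left out, 2 Mb windows and list medians with zero-count genes at their bound were added after the data were seen. Smooth trends were fitted with mgcv 1.9.3.

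The tests were tried on simulated data with 200 changed genes among 13633. Counts were drawn independently for each gene, with the same dispersion in both groups. The simulation thus had no library set apart like knockout replicate 3 and no shared shifts of genes. edgeR recovered 22% of changes of 2-fold and 65% of changes of 4-fold with 4 false calls among 91. DESeq2 recovered 53% and 83% with 48 false calls among 184, and limma-voom 21% and 62% with 4 among 87.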

Results

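The transcriptome of HT1080 cells, a human fibrosarcoma line of fibroblast-like morphology, was measured by total RNA-seq after ribosomal RNA depletion. Per the labels, 3 libraries came from wild-type (WT) cells and 3 from a TOP3B knockout clone made with CRISPR and a guide RNA against exon 2. TOP3B encodes topoisomerase III-beta, an enzyme that acts on both DNA and RNA. The stated purpose was to learn how TOP3B affects R-loops, which are RNA-DNA hybrids, and transcription across the genome. The deposited estimated counts summed to 17919106, 20414406 and 20475280 in WT replicates 1 to 3, and to 20340136, 19826713 and 18501898 in knockout replicates 1 to 3. The labels do not say that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The knockout is represented by 1 clone, so the comparison is between this clone and the WT cells.

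The TOP3B transcript itself remained present in the knockout libraries. Its counts were 536, 376 and 469 in WT and 407, 383 and 361 in the knockout, or 24.2 ± 5.82 CPM (SD, n = 3) against 19.3 ± 0.774 CPM (SD, n = 3). The log2 fold change of -0.33 ± 0.19 (SE) did not pass the test (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.342). In GENCODE v29, TOP3B lies on the minus strand of chromosome 22 from position 21957025 to 21982816 (GRCh38). A small edit in an exon need not remove the transcript, so these gene-level counts do not check the labels. Of the genes flanking TOP3B on 22q11.2, 12 were measured. PRAME, a cancer-testis antigen, fell 1.65-fold (log2 fold change -0.72 ± 0.08 SE) and the other 11 did not pass, with the same count when adjusted over the list alone. The list did not pass as a set (camera adjusted p = 0.0682, and 0.0215 without knockout replicate 3, in a range of 0.00727 to 0.264 over the alternatives).

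The WT libraries lay close together, and knockout replicates 1 and 2 did too, while knockout replicate 3 lay apart from both. Over genes above a log2 CPM of 4, the SD of log2 differences was 0.24 between knockout replicates 1 and 2, and 0.641 and 0.615 between replicate 3 and each of these. Within WT it ranged from 0.27 to 0.33. The chi-square per degree of freedom against counting noise was 12.04 or more in every pair, so no library was a copy of another. In knockout replicate 3 mitochondrially encoded transcripts took 5.70% of counts, against 8.23% to 10.0% in the other 5 libraries. Small nuclear and nucleolar RNAs took 5.31% there, against 3.38% to 4.19% elsewhere. Most of this share was RN7SK, which alone took 4.41% of counts there and 3.06% to 3.85% elsewhere.

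**Figure D1:**
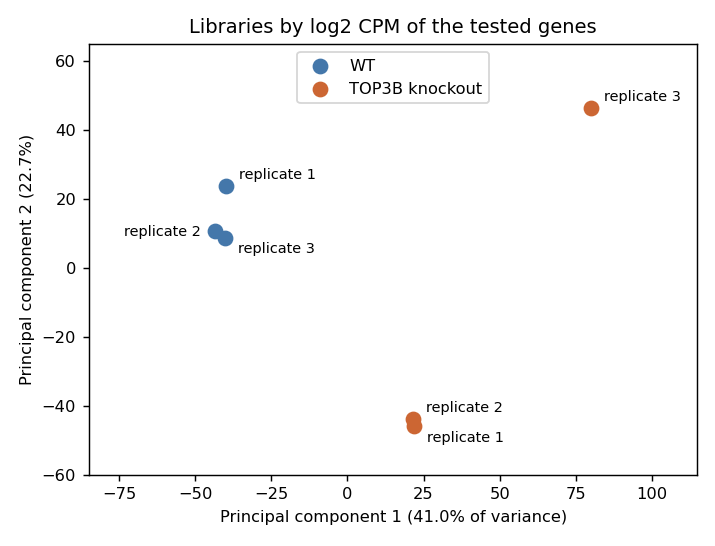
Principal components 1 (horizontal axis) and 2 (vertical axis) of log2 CPM over the 13965 tested genes, with 1 point per library, blue for WT and orange for the TOP3B knockout. The 3 WT libraries sit between -43.5 and -39.8 on component 1, knockout replicates 1 and 2 near 22, and knockout replicate 3 at 80.04.

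The main comparison asked which transcripts differed between the TOP3B knockout clone and WT cells. The matrix gene FN1 and the hypoxia gene CA12 were among those that fell, and the replication gene TYMS and the mitosis gene KIF23 among those that rose. Of 13965 genes tested, 1095 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 448 higher and 647 lower in the knockout. Of these, 465 differed at least 2-fold, 196 higher and 269 lower. In 4697 genes (33.6%) the 3 knockout libraries lay on one side of the 3 WT libraries, where chance gives 10%. The count rested on all libraries. It was 279, 223 and 256 without WT replicates 1, 2 and 3, 388 and 359 without knockout replicates 1 and 2, and 1899 without knockout replicate 3. Of 57 named genes called, 27, 25 and 28 passed without WT replicates 1, 2 and 3. Without knockout replicates 1, 2 and 3 the numbers were 35, 30 and 56. FN1 passed in all 6 of these fits, CA12 in 3, and TYMS and KIF23 in 1 each. All 1095 calls kept their sign in each of these 6 fits, and 1057 were among the 1899. DESeq2 called 2199 genes, which included all 1095. At 2-fold, the left-out fits gave 174 to 564 genes, and a test against a fold of 2 itself passed 62, with 28 higher and 34 lower.

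Several genes were close to absent from the counts of one group and well above 0 in the other. How much of a gene's transcripts was counted was not tested. The 0 counts in this and the next paragraph therefore need not mean that a gene was silent. BIRC3, an inhibitor of apoptosis in NF-kB signalling, had 0 counts in WT and 505 in the knockout, at least 162-fold higher against a floor of 3 counts over the WT group. ASTN1, a neuronal adhesion gene, had 0 against 366 counts, at least 118-fold higher. ZNF558, a zinc finger gene on chromosome 19, rose from 0.260 ± 0.0984 to 29.8 ± 1.21 CPM (SD, n = 3 each). FBLN2, the matrix protein fibulin-2, rose from 0.874 ± 0.766 to 60.8 ± 2.76 CPM, and DCC, a netrin receptor, from 0.361 ± 0.582 to 20.4 ± 2.57 CPM. The non-coding LINC02184 and IPO5P1, a pseudogene of the importin gene IPO5, completed the 7 largest rises, with log2 fold changes of 6.19 ± 0.63 and 5.55 ± 0.47 (SE). IPO5P1 reads are uncertain, because they could have been divided with its parent gene.

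In the other direction, GASK1B had 259 counts in WT and 0 in the knockout, at least 89.5-fold lower. ZNF225-AS1 had 276 against 0, at least 95.4-fold lower. SCIN, an actin-severing protein, had 1065 counts in WT and 3 in the knockout, a ratio of 368 (95% exact binomial interval 126 to 1788, for counting error only). LIPG, an endothelial lipase, fell from 24.5 ± 2.52 to 0.321 ± 0.255 CPM (SD, n = 3 each). ACOT2, a mitochondrial acyl-CoA thioesterase with a close paralog, fell from 21.2 ± 2.25 to 0.519 ± 0.0755 CPM. CNTN1, a neuronal contactin, fell from 11.6 ± 0.465 to 0.337 ± 0.133 CPM, and CALB2, the calcium-binding calretinin, from 4.94 ± 0.624 to 0.150 ± 0.0496 CPM. Whether the counting used strand is not given in the sources used here, so the antisense ZNF225-AS1 cannot be separated from its partner gene. These 14 genes passed in each of the 6 fits without 1 library, except DCC. It passed in 2 of the 6, without WT replicate 3 or knockout replicate 3, and its adjusted p was 0.0528, 0.0752, 0.0549 and 0.0617 without WT replicates 1 and 2 and knockout replicates 1 and 2.

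Some extracellular matrix transcripts were lower in the knockout. Of 39 measured matrix genes 11 fell, 1 rose and 27 did not pass, with a median log2 fold change of -0.34 (16 fell and 1 rose when adjusted over the list alone). FN1, which encodes fibronectin, fell 3.70-fold from 11750 ± 769 to 3174 ± 614 CPM (SD, n = 3 each), with a log2 fold change of -1.89 ± 0.15 (SE). COL1A1, a chain of type I collagen, fell from 6.20 ± 0.433 to 1.33 ± 0.507 CPM, and the riser was FBLN2. Of 19 matrix proteases and inhibitors 4 fell and 1 rose (6 and 1 when adjusted over the list alone). The gelatinase gene MMP9 fell 5.74-fold from 75.4 ± 2.18 to 13.1 ± 2.12 CPM, while ADAMTS12 rose from 0.286 ± 0.225 to 3.02 ± 0.381 CPM. Of 18 mesenchymal markers 3 fell and 1 rose (7 and 1 when adjusted over the list alone). The riser was CDH11, the mesenchymal cadherin-11, at 201.0 ± 6.52 against 825 ± 72.8 CPM, or 4.10-fold. VIM, the intermediate filament vimentin and a member chosen here after its values were seen, was at 11670 ± 594 and 11520 ± 173 CPM and did not pass.

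Of 23 measured targets of TGF-beta and YAP, 6 fell, 1 rose and 16 did not pass (7 fell and 2 rose when adjusted over the list alone). TAGLN, the actin-binding transgelin, fell 4.95-fold from 76.9 ± 11.6 to 15.6 ± 1.17 CPM (SD, n = 3 each). ID1, an inhibitor of differentiation, rose 1.59-fold with a log2 fold change of 0.67 ± 0.12 (SE). All 4 lists were called lower as sets by camera with a preset correlation of 0.01, with adjusted p of 0.00155 for matrix, 0.00690 for proteases, 0.0138 for mesenchymal markers and 0.0158 for TGF-beta and YAP targets. None passed when the correlation was estimated, with adjusted p = 0.152 with an estimated correlation for the first 3 and adjusted p = 0.281 with an estimated correlation for the TGF-beta and YAP targets. The TGF-beta and YAP targets also lost their call, at an adjusted p of 0.171, when genes of the 5 shifted chromosomes were left out, where the remaining 17 members had a median of -0.09. The medians of the 4 lists were -0.53, -0.40, -0.68 and -0.54 without knockout replicate 3. Of the genes named here, FN1, MMP9, CDH11, TAGLN and FBLN2 passed with each library left out. COL1A1, ADAMTS12 and ID1 passed in 2, 2 and 1 of the 6 fits without 1 library. Their edgeR adjusted p reached 0.0696, 0.0917 and 0.115 without WT replicate 2, 2 and 3.

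**Figure D2:**
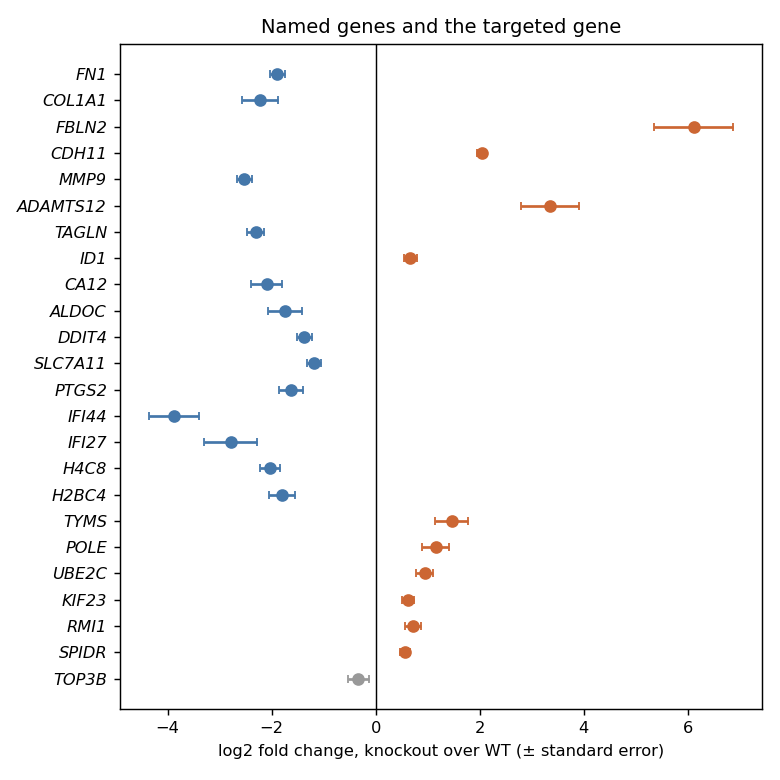
Log2 fold change of 24 named genes, knockout over WT (horizontal axis), with bars for the standard error and n = 3 libraries per group. Orange points rose, blue points fell and the grey point did not pass an adjusted p of 0.05. FN1, MMP9 and TAGLN lie at -1.89, -2.52 and -2.31, CDH11 at 2.04, and the targeted gene TOP3B at -0.33.

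Some genes of DNA replication and mitosis were higher in the knockout. Of 45 measured genes of replication and S phase 7 rose and none fell (13 rose when adjusted over the list alone), with a median log2 fold change of 0.63. TYMS, the thymidylate synthase, rose 2.75-fold from 7.63 ± 1.02 to 21.0 ± 9.35 CPM (SD, n = 3 each). It was at 15.59, 15.56 and 31.78 CPM in knockout replicates 1, 2 and 3. Its log2 fold change was 1.46, and 1.02 without knockout replicate 3. POLE, the leading-strand polymerase, rose 2.23-fold from 4.23 ± 0.872 to 9.44 ± 1.91 CPM. Of 39 mitosis genes 3 rose and none fell (4 rose when adjusted over the list alone), with a median of 0.50. UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, rose 1.92-fold and the kinesin KIF23 rose 1.54-fold, with log2 fold changes of 0.94 ± 0.17 and 0.62 ± 0.11 (SE). Of 12 measured replication-dependent histone genes, 4 fell and none rose (6 fell when adjusted over the list alone). Those that fell included H4C8, 4.08-fold lower at 3.24 ± 0.438 against 13.3 ± 1.13 CPM, and H2BC4, 3.48-fold lower. The 4 that fell are among 8 members on shifted chromosomes, with a median of -1.26, and lie on chromosome 6. The median of that chromosome, -0.27, is smaller in size than their falls, but the list rests on these members. The 4 members elsewhere had a median of -0.07 and none passed in edgeR's test. Histone genes are near-identical copies, so their counts are uncertain. The annotated spans run from 26277609 to 26285638 for H4C8 and from 26114873 to 26123926 for H2BC4 (GRCh38). Which transcripts within these spans were counted was not tested, so the falls need not be of the canonical histone mRNAs.

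The camera adjusted p was 2.72e-08 for replication, 3.62e-06 for mitosis and 0.00690 for histones. None of the 3 lists passed with adjusted p = 0.0563, 0.152 and 0.152 with an estimated correlation, in that order. Without knockout replicate 3 the medians were 0.57, 0.48 and -0.84. In that fit 7 of 46 replication genes and 10 of 39 mitosis genes rose and none fell, while 6 of 12 histone genes fell and none rose. Among the genes named, H4C8 passed with each library left out. TYMS and KIF23 passed in 1 of the 6 fits without 1 library, UBE2C in 2, H2BC4 in 4 and POLE in none. The edgeR adjusted p reached 0.159 for TYMS, 0.104 for UBE2C and 0.0631 for H2BC4 without WT replicate 2. It reached 0.138 for POLE and 0.109 for KIF23 without WT replicate 3.

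Topoisomerases and their partners, R-loop factors and DNA damage genes bear on the stated purpose. Of 13 measured topoisomerase-related genes, RMI1 and SPIDR rose and 11 did not pass, with the same count when adjusted over the list alone. RMI1, a partner of TOP3A and the BLM helicase, rose 1.64-fold from 27.4 ± 4.28 to 45.0 ± 3.91 CPM (SD, n = 3 each). SPIDR, a scaffold of homologous recombination, rose 1.48-fold from 80.1 ± 5.93 to 119 ± 6.39 CPM. The set was called higher (camera adjusted p = 0.0275, and adjusted p = 0.195 with an estimated correlation), and passed in 3 of the 6 fits without 1 library, with the call lost without WT replicate 3 and knockout replicates 1 and 2 and an adjusted p up to 0.0726. Of 39 R-loop factors, FANCA rose, THOC5 and ZC3H11A fell and 36 did not pass, with the same count when adjusted over the list alone. FANCA, a Fanconi anaemia gene, rose 1.71-fold and THOC5, a subunit of the mRNA export complex THO, fell 1.53-fold, with log2 fold changes of 0.78 ± 0.14 and -0.61 ± 0.09 (SE). ZC3H11A, an mRNA export factor named after its value was seen, had a log2 fold change of -0.59. The set did not pass (camera adjusted p = 0.215). None of the 14 genes whose loci are common R-loop test sites passed, at an edgeR adjusted p over all genes or when adjusted over the list alone, while 4 had an unadjusted p under 0.05 and DESeq2 called 1. The nuclear non-coding RNA NEAT1 was at 901 ± 80.7 and 736 ± 139 CPM, and the cyclin gene CCND1 at 356 ± 107 and 859 ± 878 CPM, the latter set by 1873 CPM in knockout replicate 3. For this list the median of -0.07 and the mean of 0.13 differed in sign, and camera gave the lower direction at an adjusted p of 0.452.

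Of 29 p53 targets 5 rose and 1 fell (8 and 1 when adjusted over the list alone). XPC, a nucleotide excision repair gene, rose 2.05-fold with a log2 fold change of 1.03 ± 0.19 (SE), and the decoy receptor TNFRSF10C fell 1.87-fold. Of 34 DNA repair genes 5 rose and 1 fell (6 and 1 when adjusted over the list alone). The checkpoint kinase CHEK2 rose 1.97-fold and LIG4, the ligase of end joining, fell 1.63-fold. Neither list passed as a set, each with a camera adjusted p of 0.0682. With fry, which does not compare a list with other genes, the adjusted p was 0.0123 for p53 targets, in a range up to 0.281 over the alternatives. For DNA repair the camera adjusted p was 0.00625 without knockout replicate 3, in a range up to 0.386 over the alternatives, where the median was 0.47 in place of 0.18. RMI1, SPIDR, FANCA, THOC5, XPC, TNFRSF10C, CHEK2 and LIG4 each failed to pass in at least 1 fit without a WT replicate. Their edgeR adjusted p reached up to 0.150. THOC5 passed in 2 of the 6 fits without 1 library, and each of the others in 1.

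Of 30 measured hypoxia and glycolysis genes 8 fell and none rose (10 fell and 1 rose when adjusted over the list alone), with a median log2 fold change of -0.18. The carbonic anhydrase gene CA12 fell 4.28-fold from 120 ± 3.50 to 28.1 ± 11.1 CPM (SD, n = 3 each), and the aldolase gene ALDOC 3.33-fold from 17.3 ± 3.03 to 5.19 ± 2.19 CPM. The camera adjusted p was 0.00192, and adjusted p = 0.152 with an estimated correlation. The glycolytic enzyme gene GAPDH, chosen after its values were seen, was at 965 CPM in knockout replicate 3 and at 161 to 285 CPM in the other libraries, and did not pass. Of 26 ATF4 and amino acid response genes 3 fell and none rose, with the same count when adjusted over the list alone. DDIT4, an inhibitor of mTORC1 signalling, fell 2.59-fold and SLC7A11, the cystine transporter, fell 2.27-fold from 398 ± 42.3 to 175 ± 22.5 CPM. This set did not pass with camera (adjusted p = 0.176) and passed with fry (adjusted p = 0.0349), in a range up to 0.439 over the alternatives. DDIT4 and SLC7A11 passed with each library left out, while CA12 passed in 3 and ALDOC in 2 of the 6 fits. The edgeR adjusted p of CA12 reached 0.0608 and that of ALDOC 0.104 without WT replicate 2.

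Of 20 NF-kB and inflammation genes 2 rose and 2 fell (4 and 2 when adjusted over the list alone). BIRC3 rose, and PTGS2, the inducible cyclooxygenase, fell 3.11-fold from 62.6 ± 11.3 to 20.2 ± 5.05 CPM (SD, n = 3 each). Of 27 interferon-stimulated genes IFI44 and IFI27 fell and 25 did not pass, with the same count when adjusted over the list alone. IFI44 was at 2.05 ± 0.765 and 0.134 ± 0.0272 CPM, and IFI27 at 6.47 ± 1.22 and 0.932 ± 0.541 CPM. Among 19 immediate early genes FOSL1, a subunit of AP-1, rose 1.94-fold and 18 did not pass (3 rose when adjusted over the list alone). None of the 15 genes of MHC class I presentation passed in edgeR's test, over all genes or when adjusted over the list alone, while 2 had an unadjusted p under 0.05 and DESeq2 called 1. TAPBP was at 112 ± 2.65 and 89.6 ± 60.8 CPM and passed at a log2 fold change of -1.03 without knockout replicate 3 (adjusted p = 0.0118, in a range up to 0.997 over the alternatives), and B2M was at 88.8 ± 18.6 and 77.8 ± 25.4 CPM. The camera adjusted p of these 4 sets was 0.779, 0.168, 0.215 and 0.355, in the order given, and fry passed the interferon genes (adjusted p = 0.0160, in a range up to 0.289 over the alternatives). IFI27, FOSL1 and PTGS2 passed in 1, 3 and 5 of the 6 fits without 1 library. Their edgeR adjusted p reached 0.0979, 0.0757 and 0.0519 without WT replicate 3, 2 and 3.

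Genes of axons and synapses changed in both directions. Of 40 measured 6 fell and 2 rose (10 and 2 when adjusted over the list alone), with a median log2 fold change of -0.37. CNTN1 fell and DCC rose, as given above, and members such as SCN2A, a sodium channel gene named after its value was seen, fell less (log2 fold change -0.61). The set was called lower (camera adjusted p = 0.00690, and adjusted p = 0.257 with an estimated correlation). Of 13 germline and cancer-testis genes 2 fell and 1 rose (3 and 1 when adjusted over the list alone), including PRAME and SSX3, which rose 1.72-fold. SSX3 belongs to a family of near-identical genes and is uncertain. Of 401 zinc finger genes with a ZNF symbol 21 rose and 10 fell (27 and 14 when adjusted over the list alone). Without knockout replicate 3, 26 of 410 rose and 22 fell. ZNF558 rose the most, and ZNF585A fell 3.86-fold from 14.8 ± 0.532 to 3.83 ± 1.04 CPM (SD, n = 3 each). Neither set passed, with camera adjusted p of 0.115 and 0.520, while fry passed the ZNF genes (adjusted p = 0.0160, in a range up to 0.676 over the alternatives). SSX3 passed in 1 of the 6 fits without 1 library, with an adjusted p up to 0.0731 without WT replicate 2.

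Markers of other cell types were few and mostly low. Of 9 measured colon epithelial markers, MUC1 fell 3.23-fold from 18.3 ± 0.456 to 5.66 ± 0.735 CPM (SD, n = 3 each) and 8 did not pass, with the same count when adjusted over the list alone. Its median was 0.26, its mean 0.05 and the direction of the set test lower (camera adjusted p = 0.921), and the median was -0.14 without knockout replicate 3. KRT8 at 92.7 ± 4.48 and 90.5 ± 8.84 CPM was the most abundant, and CDH1, the epithelial cadherin, stood at 1.97 ± 0.428 and 1.63 ± 0.451 CPM. Both were chosen after their values were seen. Of 3 blood markers none passed in edgeR's test (2 fell when adjusted over the list alone), while 2 had an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 1. ITGB2 was at 17.4 ± 2.31 and 11.1 ± 0.386 CPM, and CSF1R at 4.80 ± 1.06 and 0.811 ± 0.710 CPM. Of 4 endothelial and muscle markers TIE1, an endothelial receptor, rose 1.73-fold (2 rose when adjusted over the list alone). TIE1 passed in 1 of the 6 fits without 1 library, with an edgeR adjusted p up to 0.0823 without WT replicate 2. Both lists had fewer than 5 measured members and were not tested as sets.

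Housekeeping groups did not pass as sets. Of 83 ribosomal protein genes 4 rose and 2 fell (2 and 1 when adjusted over the list alone), with RPS25 at 1.61-fold higher and RPS12 at 1.85-fold lower. Without knockout replicate 3, 6 of the 83 genes rose and 9 fell. These genes have many processed pseudogenes and are uncertain. RPL18, chosen after its values were seen, was at 553 CPM in knockout replicate 3 and at 48.01 to 55.8 CPM elsewhere. Of 31 ribosome biogenesis and MYC genes 2 rose and 1 fell, with the same count when adjusted over the list alone. GNL3 rose 1.58-fold and NOLC1 fell 1.40-fold. Of 16 hosts of small nucleolar RNAs 3 rose (5 rose and 1 fell when adjusted over the list alone), including TAF1D at 1.76-fold and SNHG3 at 1.65-fold. Of 25 cholesterol and fatty acid synthesis genes, the desaturase genes FADS1 and FADS2 rose 1.93-fold and 1.45-fold. The count was the same when adjusted over the list alone. FADS1 lies within FADS2 on the opposite strand, and use of strand is not given, so their counts cannot be separated. Both lie on chromosome 11, called higher as a set, in a 2 Mb window where 7 of 28 genes rose. Of 15 heat shock genes DNAJB4 fell 1.85-fold, also when adjusted over the list alone. Without knockout replicate 3 the medians of the ribosome biogenesis and cholesterol lists went from 0.045 and 0.043 to -0.068 and -0.055. The camera adjusted p of these 5 sets was 0.262, 0.679, 0.176, 0.779 and 0.520, in the order given.

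None of the 17 unfolded protein response genes passed in edgeR's test, over all genes or when adjusted over the list alone, while 5 had an unadjusted p under 0.05 and DESeq2 called 5. CANX was at 2428 ± 36.8 and 2568 ± 70.7 CPM (SD, n = 3 each), and XBP1 at 233 ± 9.70 and 177 ± 26.3 CPM, with an adjusted p of 0.00966 without knockout replicate 3, in a range up to 0.253 over the alternatives. None of the 13 mitochondrially encoded or 9 structural RNAs passed in the same ways, while 2 and 5 had an unadjusted p under 0.05 and DESeq2 called 1 and 2. MT-CO1 was at 25040 ± 1776 and 23870 ± 7054 CPM, MT-ND4 at 8284 ± 102 and 8092 ± 2750 CPM, RN7SK at 35960 ± 4055 and 35170 ± 5835 CPM, and RMRP at 6276 ± 605 and 7904 ± 1073 CPM. The wide knockout spread of the mitochondrial genes goes with the lower mitochondrial share of knockout replicate 3, without which their median went from -0.095 to 0.129. That of the unfolded protein response went from 0.081 to -0.094. Camera gave an adjusted p of 0.779, 0.617 and 0.0682 for the 3 sets. Genes named in this and the preceding paragraph and called in edgeR's test each failed in at least 1 fit without a WT replicate. TAF1D passed in 5 of the 6 fits without 1 library, FADS1 in 3, and RPS12 and FADS2 in 2. RPS25, GNL3, NOLC1, SNHG3 and DNAJB4 passed in 1, and the edgeR adjusted p reached up to 0.178.

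**Figure D3:**
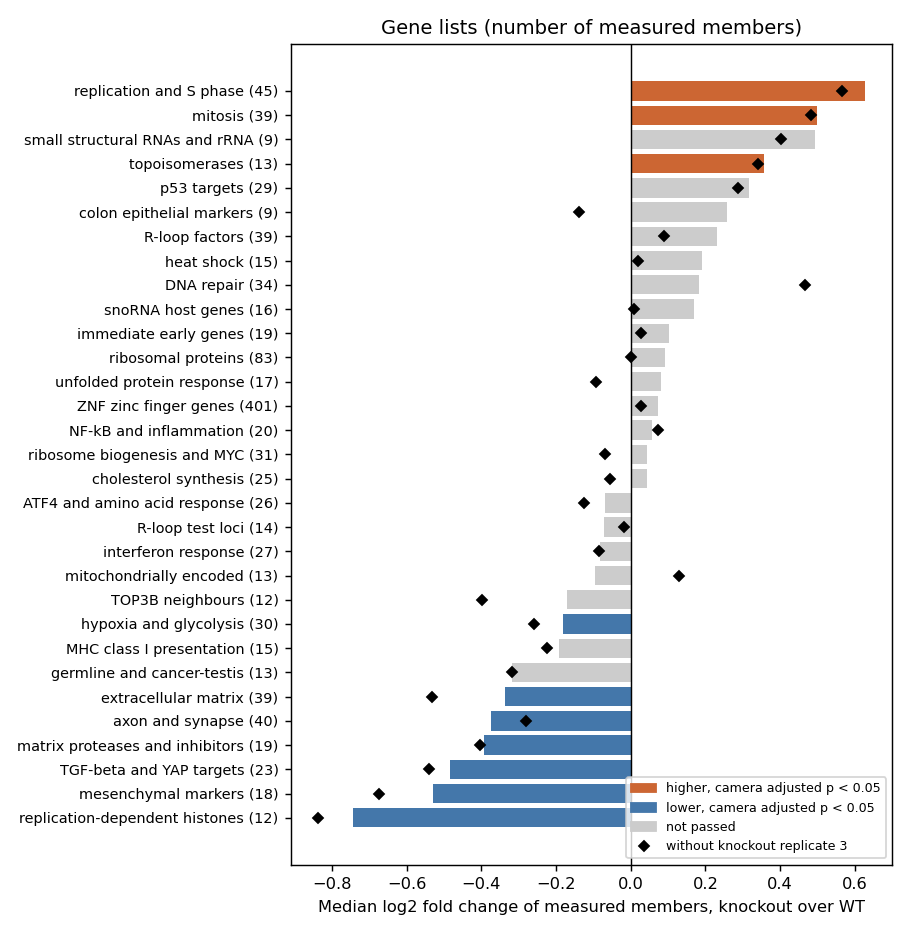
Median log2 fold change, knockout over WT (horizontal axis), of the measured members of each of the 31 gene lists tested, whose number is in parentheses. Bars are orange (higher) or blue (lower) where camera with a preset correlation of 0.01 passed and grey otherwise, and diamonds give the median without knockout replicate 3. Replication and S phase genes are at 0.63 and replication-dependent histones at -0.74.

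The change of a gene was compared with its length. Across 13901 genes, Spearman's rho between the log2 fold change and the annotated span was -0.08, a description across genes that are not independent replicates. The median log2 fold change was 0.10 in the shortest length quintile, with spans up to 8924 bp, and -0.02 in the longest, with spans from 98219 bp. Of 2780 genes each, 74 rose and 83 fell in the shortest quintile, and 96 rose and 193 fell in the longest. Without knockout replicate 3 these medians were 0.02 and -0.002, and rho was -0.02. Against the mean of the 3 WT libraries, rho was -0.004, -0.03 and -0.13 in knockout replicates 1, 2 and 3. WT libraries set against the mean of the other 2 gave -0.08 to 0.06, so the values of knockout replicates 1 and 2 lay within the range of WT libraries and that of replicate 3 outside it.

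Camera called 5 chromosomes as sets. Chromosomes 4, 6 and 10 were lower in the knockout, with median log2 fold changes of -0.18, -0.27 and -0.18, and chromosomes 11 and 20 were higher, at 0.24 and 0.31. On chromosome 6, 63 of 619 genes fell and 5 rose, and on chromosome 20, 33 of 335 rose and 10 fell. Camera with a preset correlation gave adjusted p of 0.000468, 2.23e-06, 0.000323, 0.000136 and 2.58e-06 in the order 4, 6, 10, 11 and 20. Chromosomes 6, 11 and 20 also passed with an estimated correlation (adjusted p = 0.0372, 0.00598 and 0.00598 with an estimated correlation), and chromosomes 4 and 10 did not (adjusted p = 0.0638 and 0.09999 with an estimated correlation). The medians were -0.18, -0.29, -0.18, 0.19 and 0.30 without knockout replicate 3. With the preset correlation, WT replicates 1 and 3 and knockout replicate 1 set against the other libraries also gave 5 calls. Such p-values therefore need not reflect the genotype labels. Within 5 Mb of TOP3B, 13 of 106 genes fell and 3 rose. This is 15.09% called, against 1095 of 13965 over all genes. The set did not pass (camera adjusted p = 0.219), with a median of -0.001. Camera tests a shared shift, and whether the share of called genes was raised there was not tested.

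**Figure D4:**
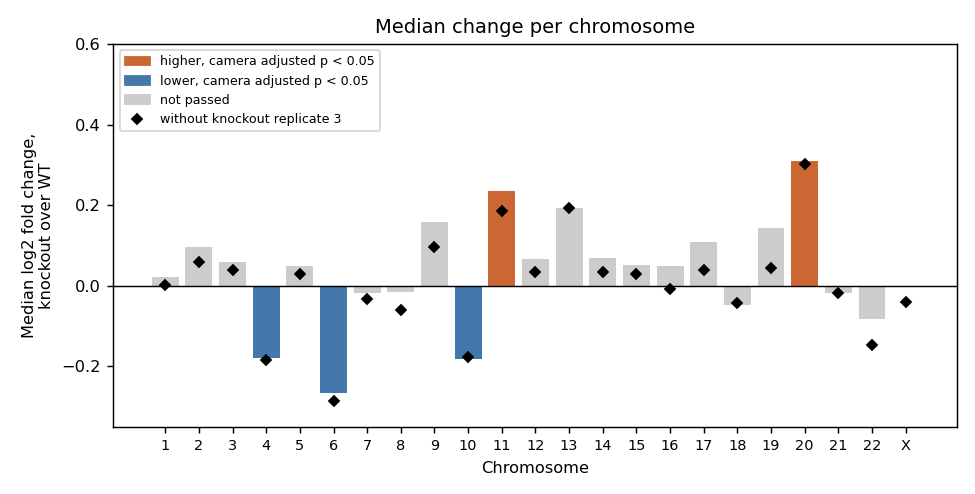
Median log2 fold change, knockout over WT (vertical axis), of the tested genes of each chromosome (horizontal axis). Bars are orange or blue where camera with a preset correlation passed and grey otherwise, and diamonds give the median without knockout replicate 3. Chromosome 6 is lowest at -0.27 and chromosome 20 highest at 0.31.

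Neighbouring genes rose together in a cluster of zinc finger genes of chromosome 19. Between 20 and 24 Mb (GRCh38), 9 of 19 measured ZNF genes rose and none fell, and all 19 had a fold change above 0. ZNF91 rose from 1.098 ± 0.849 to 30.8 ± 12.6 CPM (SD, n = 3 each), ZNF681 from 3.78 ± 0.515 to 25.5 ± 3.40 CPM and ZNF85 from 1.75 ± 0.497 to 12.9 ± 0.814 CPM. Of the other 382 ZNF genes 12 rose and 10 fell. Reads shared between related ZNF genes were not excluded, so these counts are uncertain. The 2 Mb windows behind this comparison, and the genes named from them, were chosen after the data were seen. Of 829 windows with at least 6 tested genes, 8 passed a binomial test of their risers and of their fallers, with the smaller p doubled. It was used with Benjamini-Hochberg adjustment and treats neighbouring genes as independent. The window from 22 Mb held 6 risers among 10 genes (binomial test adjusted p = 0.000340). They were ZNF675, ZNF681, ZNF726, ZNF91, the pseudogene IPO5P1 and LINC01224, so the risers were not only ZNF genes. In the window from 154 Mb on chromosome 1, 12 of 48 genes fell (binomial test adjusted p = 0.00118), among them MUC1. The falls were not confined to this window. The 610 tested genes of chromosome 1 from position 143461221 on had a median log2 fold change of -0.252 relative to all genes. The binomial test used the rates of rises and of falls over all genes, without allowing for such wider shifts.

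**Figure D5:**
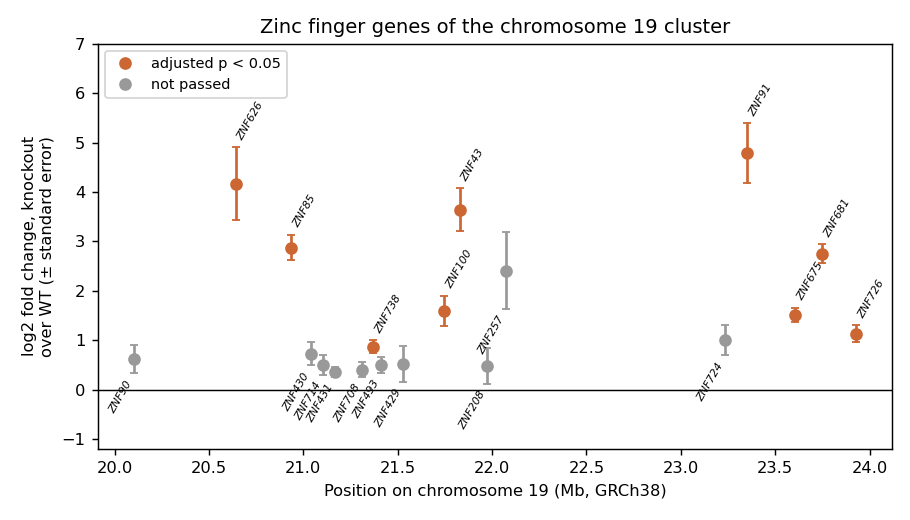
Log2 fold change, knockout over WT (vertical axis), of 19 ZNF genes by position on chromosome 19 in Mb of GRCh38 (horizontal axis), with bars for the standard error and n = 3 libraries per group. Orange points passed an adjusted p of 0.05 and grey points did not. All points lie above 0, with ZNF91 highest at 4.79.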

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

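Of 1095 genes called by edgeR, DESeq2 called all, among 2199, and the fits with 1 library left out called 223 to 1899 genes. On simulated data DESeq2 made 48 false calls among 184 and edgeR 4 among 91. These rates need not hold for the deposited data, since no simulated library lay apart from its group. At 2-fold, 465 genes became 83 with limma-trend on log2 RPKM with a pseudocount of 1, which shrinks changes of low values, and 62 when the fold of 2 was itself tested. Leaving out 1 library gave 174 to 564. The low counts without a WT library or knockout replicate 1 or 2 came with fewer samples, and 1 fewer residual degree of freedom. The higher count without knockout replicate 3 came with fewer samples too, and with less spread within the knockout. The SD of log2 differences was 0.24 between knockout replicates 1 and 2, and 0.641 and 0.615 from these to replicate 3. Whether this was the cause was not tested. The 10 list calls became 0 with an estimated correlation, where camera by construction also uses the 4 residual degrees of freedom. With fry, which does not compare a list with other genes, 15 lists passed, the 10 among them. The calls were 9 to 12 with 1 library left out. The 5 chromosome calls became 3 with an estimated correlation, and were 5 to 6 with 1 library left out, a test chosen after the data were seen. Over all results and alternatives, 1320 values kept direction and side of the threshold or moved little, 178 lost their call in the same direction, 26 gained one, 16 moved and 20 changed direction. None of these 20 was called by edgeR or camera either way, and their cause was not tested. With 1 library left out, log2 fold changes ranged from -0.025 to 1.657 for CCND1 and from -1.032 to 0.00272 for TAPBP. They ranged from -0.1821 to 0.05865 for RN7SK, from -0.2264 to 0.1483 for MT-CO1 and from -0.2639 to 0.2043 for MT-ND4. CCND1, MT-CO1 and MT-ND4 changed sign without knockout replicate 3 and TAPBP without knockout replicate 1. RN7SK did without WT replicate 1 or knockout replicate 1 or 2. MT-ND4 was at 0.01328 with library size only and at 0.01261 with sizes without the 100 most abundant genes. RN7SK was at 0.01839 with both RPKM pseudocounts, 0.003234 with upper quartile, 0.03137 with library size only and 0.02275 without the 100 most abundant genes. Among lists, the adjusted p ranged with 1 library left out from 0.109 to 0.8074 for mitochondrial genes and from 0.5126 to 0.9612 for the unfolded protein response, which changed direction without knockout replicate 3. It ranged from 0.6522 to 0.9454 for cholesterol and from 0.3847 to 0.8557 for colon markers, which changed direction without knockout replicate 2 and 1. With shifted chromosomes left out it was 0.3961 for NF-kB and 0.4773 for cholesterol, in the other direction. Depth limits genes at 0 counts to bounds, and 22% of simulated 2-fold changes were recovered. No paired analysis was possible because the knockout labels carry no replicate numbers.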

Other observations

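In all, 12 further genes, all chosen after their values were seen, were read out. The sulfatase SULF2 rose from 2.66 ± 1.80 to 65.1 ± 16.0 CPM (SD, n = 3 each), neurofascin (NFASC) 10.6-fold, the endothelial gene ESM1 5.48-fold, the transcription factor GATA4 34.1-fold and the cadherin CDH4 6.59-fold. The adhesion genes L1CAM and NRCAM fell 6.05-fold and 16.0-fold, the netrin receptor UNC5B 5.89-fold, NOTCH3 4.44-fold, the MHC class II regulator CIITA 16.1-fold, SPP1 9.80-fold and EGF 5.34-fold. With each library left out, 8 of the 12 passed throughout. CDH4 and NOTCH3 passed in 5 of the 6 fits, and CIITA and SPP1 in 2. The edgeR adjusted p of CDH4, NOTCH3, CIITA and SPP1 reached 0.0590, 0.0550, 0.0711 and 0.0843.

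The tests of depth, label and mixture for knockout replicate 3, that of this library for the chromosomes, those of the 2 sides of each chromosome and that of reads shared between zinc finger genes were chosen only after the result was seen. Knockout replicate 3 lay apart from the other 2 knockout libraries. POLDIP2, chosen after its values were seen, was at 0 CPM there and at 82.8 to 97.8 CPM elsewhere. Depth was argued against, since WT replicate 1, the shallowest library, differed from other WT libraries by an SD of at most 0.33. In 83.3% of 540 genes called at 2-fold without it, replicate 3 lay nearer to the knockout, against 5.0% to 6.2% for left-out WT libraries, which argues against a WT library under a wrong label. A first bound of 90%, missed at 2-, 4- and 8-fold (83.3%, 87.0% and 84.1%), was replaced by this comparison. Knockout replicates 1 and 2 left out alike met that bound at 2-fold (93.2% and 92.5%) and 4-fold (90.3% and 90.4%), and missed it at 8-fold (84.0% and 85.2%). A mixture with WT cells would bring the library nearer to WT, but its SDs from WT libraries were 0.698 or more, against at most 0.494 for knockout replicates 1 and 2, which argues against it as the cause. Removing a smooth trend on GC content, transcript length and span left an SD of 0.582 of 0.615, so it was not the whole cause. A difference in culture, in library preparation or in the counting of reads stays open and was not tested.

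Genes of chromosomes 4, 6 and 10 were lower and those of 11 and 20 higher. Without knockout replicate 3 at least 81.9% of each chromosome's median, relative to all genes, was kept, so it was not the whole cause. A smooth trend on GC content and length explained 0.67% of the variance of the fold changes, and at least 92.7% of each median was kept after its removal, so such a trend was not the whole cause. A copy number difference of a whole chromosome, which may arise in cloning, would shift both sides of the longest gap between gene starts. Side medians are log2 fold changes relative to the median of all genes, so a side at 0 moved like all genes. The median after the gap minus that before it was -0.069 on chromosome 6 and -0.02 on chromosome 20, with both sides shifted, which is consistent with it. It was -0.337 on chromosome 4 and 0.261 on chromosome 11, where the side before the gap was at -0.011 (95% bootstrap interval over genes -0.119 to 0.097) and 0.006 (-0.049 to 0.065), which argues against a change of the whole of either. On chromosome 10 it was -0.177, with both sides shifted unequally, and this stays open. The size of shift that a gained or lost copy would give was not set against any of these medians. On chromosome 6 the gap lay between 101430411 and 104017633, so its sides need not be the arms of the chromosome. The rule was the third tried. The first, a side under 50% of the other, excluded chromosome 10 too, and the second, a difference beyond the 0.376 of chromosome 1, excluded none, so the verdict depends on the rule. An earlier share of windows on their chromosome's side was dropped, since choosing shifted chromosomes favours it. The shifted sides were at -0.348 (-0.431 to -0.277) on chromosome 4 and 0.266 (0.233 to 0.324) on chromosome 11. Chromosome 1, not called as a set, was at 0.124 before its gap and at -0.252 (-0.318 to -0.183) after it. No test here addresses the cause of such part-chromosome shifts, copy number was not measured, and the 1 clone confounds it with the loss of TOP3B.

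In the zinc finger cluster of chromosome 19 between 20 and 24 Mb (GRCh38), 19 of 19 ZNF genes were higher, with a median log2 fold change of 1.00. Their summed level went from 153 ± 7.67 to 316 ± 6.05 CPM (SD, n = 3 each), which follows from choosing a window of risers. Without knockout replicate 3 the median was 0.793, so this library was not the whole cause. Reads moved from related genes elsewhere would lower those. The sum over the other 382 ZNF genes changed by -474.58 ± 335 CPM (SE), too wide a spread to tell a fall of the size of the rise, 163 CPM, from none. IPO5P1 and LINC01224, which are not ZNF genes, rose in this region too. Reads shared among ZNF genes would not by themselves raise them, although IPO5P1 reads could have been divided with its parent gene. For the ZNF genes, shared reads and a regional change in this clone, which may be epigenetic or genetic, both stay open. No test here separates a regional change from the loss of TOP3B.

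With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 1095 genes, 465 of them at 2-fold, and the highest other split 0 and 0. It called 10 lists and 5 chromosomes, and the highest other split 5 and 5. As many were reached by 1, 1, 1 and 2 of the 10 splits.

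Of protein-coding genes with 1 annotated transcript 17.4% were in the count table, against 82.8% with 2 and 99.2% with over 10. The levels of ACTB and VIM, both chosen after their values were seen, were 87.6 and 11670 CPM in WT. How much of a listed gene's transcripts was counted was not tested.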
